A study of Gallus gallus with 3 samples.

How the data were processed

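The series measured single-cell transcriptomes of gastrula-stage chick embryos in 3 droplet libraries. The sample titles give the stage as HH3/3plus for all 3, with the time in culture as additional incubation. Per the labels, the embryos were unablated controls of a node ablation experiment that had been lifted off the vitelline membrane and put back. They were then kept in culture for 0.5 h, 2.5 h or 5.0 h. Part of the area opaca was trimmed and the tissue was dissociated with trypsin. Each time is 1 library, and the sources used here do not say how many embryos a library holds.

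The deposited values are raw UMI counts per gene and barcode, written by Cell Ranger 6.1.2 per the file headers. The submitters' processing notes name the galGal6 build, Seurat and R 4.2.3 without saying what each was used for. The annotation is not given in the sources used here. The files hold 6940 features named by symbol, among them no mitochondrial genes that could be named, so no mitochondrial filter was applied. Chromosomes of genes were taken by symbol from a gene table of the GRCg7b assembly, which matched 6820 of the 6940 features. No coordinates from that table were used.

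Barcodes with at least 1000 UMIs and 500 genes were kept. Doublets were called in each library with Scrublet in Scanpy 1.11.5 at an expected rate of 6% and removed. They made up 3.52%, 4.34% and 7.06% of filtered barcodes at 0.5 h, 2.5 h and 5.0 h. The remaining 20670 cells were clustered together on 1500 variable genes and 30 principal components with 20 neighbours, using the Leiden method at resolution 1 (leidenalg 0.10.2). Members of 16 gene lists fixed before the data were examined were kept out of the clustering genes. The lists cover BMP targets, BMP ligands and receptors, BMP antagonists and modulators, EMT, epithelial junctions, basement membrane and matrix, cytoskeleton, FGF, WNT, NODAL and TGF-beta, Notch, HOX, guidance, cell cycle, glycolysis, and dissociation stress. The HOX list also holds CDX and MEIS genes. Of the 468 list entries 302 are in the files, as are 108 of 147 cell type markers.

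Clusters were named from markers fixed before the data were examined. Clusters of low UMI count and 1 cluster led by ANXA1 stayed unnamed. In the main clustering a class name ending in -like rests on these markers only. Clusters at other resolutions, in the scaled clustering and with list members allowed were not named from markers. Each took the class that was most frequent among its cells in the main clustering.

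For class contrasts, UMI counts were summed per library and class and tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, two-sided). The library was a block, which leaves 2 residual degrees of freedom in the design. Adjusted p is Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Only genes outside the clustering genes were counted or named. Beside list counts of 0, the counts at an unadjusted p under 0.05 and by DESeq2 are given. A class with under 50 cells in any library was not tested. The p-values measure how a class difference varied over 3 libraries that are also 3 times, so they say nothing about variation between embryos of 1 time. For the contrast by SNAI2, streak-like cells were thinned to 9000 UMIs. Cells below that depth were left out: 20 of 1202 at 0.5 h, 150 of 1205 at 2.5 h and 89 of 1183 at 5.0 h. The thinned shares of cells with SNAI2 leave out cells below that depth too.

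Comparisons between times have no replicates and no test. CPM values were computed from the deposited counts summed over the cells of a library or class and divided by their total, with exact Poisson intervals, and ratios carry exact conditional binomial intervals. Shares carry exact Clopper-Pearson intervals. All intervals are at 95% and cover counting error only. A list's median log2 ratio was placed among 10000 random lists of equal size matched on expression. Random genes were drawn independently, so they lack any shared regulation of a list's members. Lists of many kinds lay beyond the central 95% of random lists, so a percentile describes a list and does not test it.

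Named genes followed a rule fixed before the data were examined. For class contrasts it takes the 12 largest rises and the 12 largest falls among list members past the threshold with at least 10 CPM, plus CDH1, CDH2, SNAI2, BMP2, BMP4, ID1, ID2 and ID3. The rule also names BMP7, which is not analysed here, and some genes it takes are not reported here. For time it takes genes of at least 30 CPM in 1 library that differ at least 2 times between 0.5 h and 5.0 h with 2.5 h between them, up to 12 per direction. Within classes it takes list members by the same rule, up to 10 per direction. For SNAI2 status it takes the BMP targets, ligands, receptors, antagonists and modulators past the threshold, plus ID1, ID2 and ID3. Markers and sex-linked, HOX or amino acid response genes that are given with values were picked from their lists after the values were seen, and genes named without values are members of a list that passed.

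The tests were tried on simulated counts made from the real means. Of genes changed by a log2 of 1, the fits recovered 88% for streak-like against epiblast-like, 68.7% for mesoderm-like against streak-like, 77% for endoderm-like against streak-like, 99% for non-neural ectoderm-like against epiblast-like and 99% for SNAI2 status. False calls were 4.08%, 6.74%, 3.85%, 7.44% and 10.8% of calls in that order. The ratio intervals were tried on Poisson counts with drawn means and a fixed ratio, not on the real means. They held the true ratio in 94.6% of 2000 simulated genes. Since the intervals assume such counts, this checks the calculation only.

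Alternatives were DESeq2 1.42.0 and its size factors, no expression filter, no library block, each library left out, stricter cells (2000 UMIs and 1000 genes), doublets kept, Leiden resolutions of 0.5 and 2, clustering genes scaled within each library, and list members allowed among the clustering genes. For time they were TMM-scaled CPM, means over cells, all barcodes, floors of 10 and 100 CPM, and a ratio of 1.5. Other tools were R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.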

Results

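The data are 3 libraries of chick gastrula cells, 1 each after 0.5 h, 2.5 h and 5.0 h of further culture. The files hold 7831, 6529 and 8212 barcodes with 134788978, 75692648 and 117391091 UMIs in that order. The median barcode had 16941 UMIs at 0.5 h, 11784 at 2.5 h and 14275.5 at 5.0 h. After filtering, 7296, 5977 and 7397 cells remained. The series title concerns EMT and BMP signalling during cell invasion, so the comparisons centre on streak-like cells, set against epiblast-like, mesoderm-like and endoderm-like cells.

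Epiblast-like cells carried SOX3, at 833, 856 and 907 CPM over the 3 times. Streak-like cells carried T, at 1241, 2030 and 1232 CPM, and EOMES, at 163, 332 and 678 CPM. Mesoderm-like cells carried KDR and HAND2. Endoderm-like cells carried SOX17, at 3415, 4114 and 3529 CPM, with HHEX and CER1, and their definitive endoderm and hypoblast markers could not be separated. Yolk sac endoderm-like cells carried APOA1, non-neural ectoderm-like cells TFAP2A and GATA2, and 74 germ cell-like cells DAZL and DDX4. The main embryonic classes came from a different cluster in each library: epiblast-like from clusters 1, 6 and 2, streak-like from 8, 7 and 9, and mesoderm-like from 0, 4 and 3, in the order of time. Yolk sac endoderm-like cells came mostly from cluster 10 at 0.5 h and 5.0 h and from cluster 12 at 2.5 h. The streak-like cells also differed in markers between libraries, with GSC at 53.2, 39.0 and 284 CPM and LHX1 at 15.6, 63.8 and 76.0 CPM. Many of these markers could help define the clusters and are given here as descriptions.

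Epiblast-like cells were 27.4% of cells at 0.5 h (95% interval 26.4 to 28.5), 21.9% at 2.5 h (20.9 to 23.0) and 27.02% at 5.0 h (26.01 to 28.1). In the same order, streak-like cells were 16.5% (15.6 to 17.3), 20.2% (19.1 to 21.2) and 15.99% (15.2 to 16.8), and mesoderm-like cells 28.8% (27.8 to 29.9), 23.3% (22.2 to 24.3) and 25.02% (24.04 to 26.03). Endoderm-like cells were 10.3% (9.57 to 10.97), 4.65% (4.13 to 5.22) and 4.50% (4.04 to 5.00). Yolk sac endoderm-like cells were 4.07% (3.63 to 4.55), 18.4% (17.4 to 19.4) and 11.2% (10.5 to 11.96), and non-neural ectoderm-like cells 3.00% (2.62 to 3.42), 2.29% (1.93 to 2.70) and 6.77% (6.21 to 7.37). How much of the area opaca each library holds is not given in the sources used here, and the shares of a library add to a fixed total. Unnamed low-UMI cells were 7.72%, 7.29% and 6.94%. At Leiden resolution 0.5 no cluster had streak-like or non-neural ectoderm-like as the most frequent main class of its cells, so neither class was assigned. With list members allowed among the clustering genes, non-neural ectoderm-like cells were 6.13% at 0.5 h and 3.23% at 5.0 h, the opposite order.

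**Figure D1:**
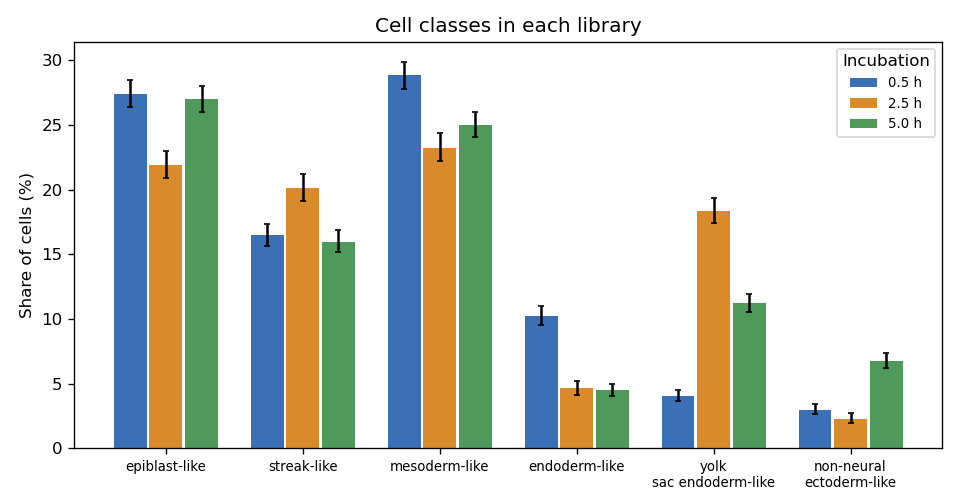
Share of filtered cells (%) in 6 cell classes for the libraries at 0.5 h, 2.5 h and 5.0 h, with exact 95% intervals that cover counting error only. The yolk sac endoderm-like share was 4.07%, 18.4% and 11.2%.

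Streak-like cells were compared with epiblast-like cells to see what differs where cells enter the streak. SNAI2, a transcription factor of EMT, averaged 538 ± 191 CPM (SD, n = 3 libraries) in streak-like cells and 20.2 ± 4.38 CPM in epiblast-like cells, a log2 fold change of 4.70 ± 0.28 (SE). CDH2, which encodes N-cadherin, was higher by 3.04 ± 0.47. CDH1, which encodes E-cadherin, was at 112 ± 7.61 and 138 ± 15.9 CPM and did not pass (log2 fold change -0.26, edgeR adjusted p 0.0500). BMP2 was higher by 3.23 and BMP4 by 1.07, and the BMP antagonist CHRD by 4.76. ID1 and ID3, transcriptional targets of BMP, were lower at -1.22 and -1.12, and ID2 did not pass (-0.51, adjusted p 0.150).

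Of 9 measured BMP targets, 5 were higher (MSX1, MSX2, ID4, SMAD6 and ATOH8) and 2 lower, and adjusted over the list alone the counts were also 5 and 2. Of 14 BMP antagonists and modulators 7 were higher, ADMP among them, and 1 lower (8 and 1 adjusted over the list alone), with FST at 3.75 and BMPER at -1.92. Of 11 BMP ligands and receptors 6 were higher and 0 lower in edgeR (6 and 0 adjusted over the list alone, 0 lower at an unadjusted p under 0.05, and 5 and 0 in DESeq2). Of 19 FGF genes 11 were higher and 4 lower (13 and 4 adjusted over the list alone), with FGF3 at 6.09, FGF19 at 5.27, FGF4 at 5.05, FGF18 at 4.37 and FGF8 at 4.03, and the receptors FGFR3 at -1.56 and FGFR2 at -1.03. Of 25 WNT genes 13 were higher and 3 lower (15 and 4 adjusted over the list alone), with WNT8A at 4.50, SFRP2 at -1.47 and FRZB at -1.30. Of 20 EMT genes 9 were higher and 3 lower (10 and 3 adjusted over the list alone), TAGLN among the latter at -1.53. Of 15 epithelial junction genes 2 were higher and 3 lower (2 and 4 adjusted over the list alone).

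Of 27 matrix and integrin genes 7 were higher and 3 lower (8 and 5 adjusted over the list alone). ITGA6, which encodes a laminin-binding integrin chain, was at -2.09 and DAG1, which encodes dystroglycan, at -1.46. Of 24 guidance genes 8 were higher and 4 lower (12 and 5 adjusted over the list alone), with PDGFRA at 5.40 and EFNA5 at -1.22. Of 15 NODAL and TGF-beta genes 6 were higher and 1 lower (6 and 1 adjusted over the list alone), with LEFTY1 at 6.83. Of 8 HOX list genes 4 (CDX1, CDX4, HOXA2 and HOXB1) were higher and 0 lower in edgeR (6 and 0 adjusted over the list alone, 0 lower at an unadjusted p under 0.05, and 5 and 0 in DESeq2). Of 6 Notch genes DLL1 was higher at 4.10 and HES5 lower at -1.86, with the same counts adjusted over the list alone. Counts higher and lower were 6 and 3 of 27 cell cycle genes, 3 and 4 of 25 cytoskeleton genes, and 1 and 4 of 18 glycolysis genes, the same when adjusted over the list alone. Of 15 dissociation stress genes 0 passed in edgeR, over all genes or adjusted over the list alone, while 1 was higher and 4 lower at an unadjusted p under 0.05 and DESeq2 called 0 higher and 3 lower.

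Over all genes, 320 were higher and 302 lower of 3580 tested outside the clustering genes (edgeR, adjusted p under 0.05). The counts were 96 and 69 without the 2.5 h library, 75 and 46 without the 5.0 h library, 61 and 44 without the library block, 90 and 105 at Leiden resolution 2, and 760 and 798 with clustering genes scaled within each library. Among the named genes, CDH2 (edgeR adjusted p 0.0947), BMP4 (0.0507), ID1 (0.0603), FST, DAG1, EFNA5 and FGFR2 no longer passed without the 5.0 h library and ID1 (0.0722) without the 2.5 h library, while CDH1 passed at -0.34 (0.0227) without the 0.5 h library. Without the library block DLL1, BMPER, FGFR3, TAGLN, ID1, ID3 (0.0565) and BMP4 (0.345) no longer passed, and at Leiden resolution 2 CHRD (0.168), FGF18, FGF8, FST, BMPER, ID1 and CDH2 (0.0539) did not. With the scaled clustering BMP4 no longer passed (0.0576), and ID2 at -0.82 (0.0106) and CDH1 at -0.42 (0.00258) did. CDH1 also passed in DESeq2 (0.0159), with its size factors in edgeR, with no expression filter and with doublets kept.

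**Figure D2:**
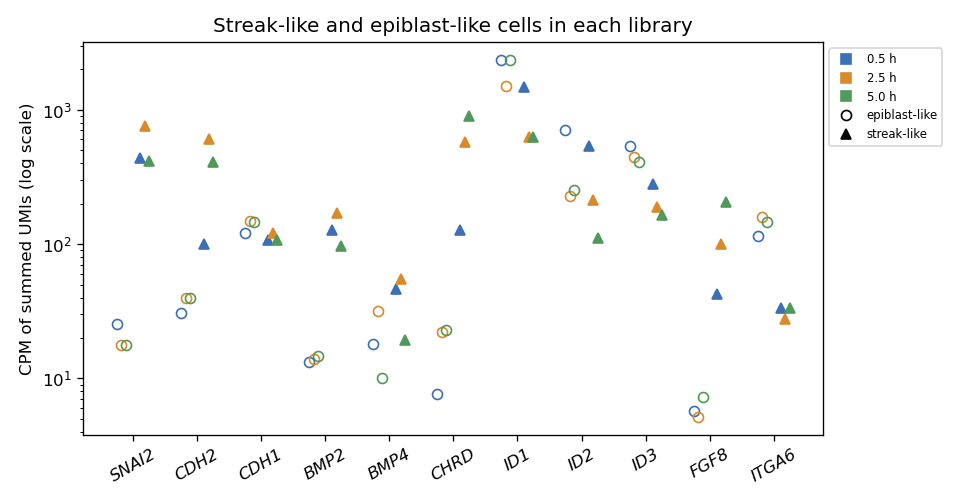
CPM of summed UMIs (log axis) of 11 genes in epiblast-like cells (open circles) and streak-like cells (triangles), 1 point per library. SNAI2 averaged 538 CPM in streak-like and 20.2 CPM in epiblast-like cells.

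Mesoderm-like cells were compared with streak-like cells, though the classes do not cleanly part cells that have left the streak from those within it. T, a streak marker, had a log2 fold of 1.87 over the rest of the library in the 5.0 h mesoderm-like cluster 3. It had 1.37 in the 0.5 h streak-like cluster 8 and 2.51 in the 2.5 h streak-like cluster 7. T was not among the 30 leading genes of the 5.0 h streak-like cluster 9, of which the last, EPHA4, had 1.39. That cluster was led by ADMP, CHRD, THPO and GSC, so at 5.0 h T led the mesoderm-like more than the streak-like cluster. MSGN1, a mesoderm marker, had 3.22 in cluster 7. TWIST1, a mesenchymal transcription factor, was higher by 4.29 ± 0.58 on the log2 scale (100.0 ± 49.4 against 5.44 ± 3.55 CPM), and VEGFA by 3.33 ± 0.09. BMP2 was higher by 1.47, with SMAD1, a transducer of BMP signals, at 1.02 and the BMP-induced inhibitor SMAD6 at 2.31. ADMP, which encodes a BMP-type ligand of the organizer, was lower at -5.39 and VIM, which encodes vimentin, at -1.99. SNAI2 was at 745 ± 136 CPM in mesoderm-like cells and did not pass (0.56, edgeR adjusted p 0.188). Neither did CDH1 at -0.31, CDH2 at 0.58, BMP4 at -0.35, ID1 at 0.49, ID2 at 0.47 or ID3 at -0.11, and of these CDH2, BMP4, ID1, ID2 and ID3, as SNAI2, took opposite directions in different libraries, each beyond counting error.

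Of 19 FGF genes 3 were lower (DUSP6 at -1.19, FGFR1 at -1.25 and ETV5 at -0.77) and 0 higher in edgeR. Adjusted over the list alone 7 were lower and 1 higher, at an unadjusted p under 0.05 10 and 2, and in DESeq2 8 and 2. Of 15 epithelial junction genes JUP was lower at -0.98 and 0 were higher in edgeR. Adjusted over the list alone 8 were lower and 1 higher, at an unadjusted p under 0.05 9 and 1, and in DESeq2 8 and 1. Of 27 matrix genes HAPLN1 and ITGB3 were higher at 2.37 and 2.77 and GPC1 lower at -0.85 (2 and 4 adjusted over the list alone). Of 22 EMT genes 1 was higher and 3 lower, THY1 at -1.77 among them (4 and 4 adjusted over the list alone). CXCL12, which encodes a chemokine, was higher at 1.47, and the WNT inhibitors FRZB and SFRP2 were lower at -1.14 and -0.67. Of 13 HOX list genes 0 passed over all genes in edgeR, while 9 were higher and 0 lower both adjusted over the list alone and at an unadjusted p under 0.05, and DESeq2 called 7 higher.

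Of 9 BMP targets 1 was higher and 0 lower in edgeR (2 and 0 adjusted over the list alone, 3 and 1 at an unadjusted p under 0.05, 3 and 1 in DESeq2). Of 11 BMP ligands and receptors 2 were higher and 0 lower (4 and 0 adjusted over the list alone, 4 and 1 unadjusted, 4 and 0 in DESeq2). Of 14 BMP antagonists and modulators 0 were higher, and the ligand ADMP was the 1 lower (the same adjusted over the list alone, 2 and 4 unadjusted, 0 and 2 in DESeq2). Of 18 glycolysis genes 0 were higher and SLC16A1 was lower at -0.48 (6 and 3 adjusted over the list alone, 8 and 3 unadjusted, 7 and 3 in DESeq2). Of 15 NODAL and TGF-beta genes 0 passed (3 and 1 adjusted over the list alone, 5 and 4 unadjusted, 4 and 2 in DESeq2), and of 6 Notch genes 0 passed (0 and 3 by each of these counts). Of 25 cytoskeleton genes 0 passed (1 and 3 adjusted over the list alone, 3 and 6 unadjusted, 1 and 6 in DESeq2). Of 27 cell cycle genes CENPF was lower at -0.71 and 0 were higher (0 and 2 adjusted over the list alone, 4 and 4 unadjusted, 2 and 2 in DESeq2). Of 24 guidance genes 2 were higher and 0 lower (3 and 3 adjusted over the list alone, 3 and 5 unadjusted, 3 and 4 in DESeq2). Of 25 WNT genes 0 were higher and 2 lower (4 and 4 adjusted over the list alone, 4 and 6 unadjusted, 4 and 5 in DESeq2). Of 15 dissociation stress genes 0 passed over all genes or adjusted over the list alone (0 and 1 unadjusted and in DESeq2).

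In all, 25 genes were higher and 37 lower of 3574 (edgeR, adjusted p under 0.05), and 880 had an unadjusted p under 0.05. Without the 2.5 h library 0 passed in edgeR, none of the named genes among them, and 331 had an unadjusted p under 0.05. The counts were 10 and 14 without the 0.5 h library, where BMP2 (adjusted p 0.0517), SMAD1, SMAD6, CXCL12, HAPLN1, DUSP6, FRZB, GPC1, ETV5, SFRP2 and SLC16A1 no longer passed, CDH2 turned to -0.089 and BMP4 to 0.14, and 62 and 73 without the 5.0 h library, where ID3 turned to 0.018. At Leiden resolution 2 the counts were 13 and 18, and TWIST1 (0.0501), ITGB3, CXCL12, BMP2 (0.0631), SMAD1, ADMP (0.1002), VIM, THY1, DUSP6, JUP, CENPF, SFRP2 and SLC16A1 no longer passed. Without the library block 15 genes were higher, and SMAD1, FGFR1, DUSP6, FRZB, JUP, GPC1, CENPF, SFRP2 and SLC16A1 no longer passed, nor did FRZB and SLC16A1 with DESeq2 size factors in edgeR. DESeq2 called 234 and 186, and classes from clustering genes scaled within each library gave 666 and 606, with ID1 passing at 0.68 (0.0361) and ID2 at 0.77 (0.00366).

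Endoderm-like cells were also compared with streak-like cells. Their definitive endoderm and hypoblast markers could not be separated, so the contrast is not read as a route out of the streak. CXCR4, the receptor of the chemokine CXCL12, was higher by 5.27 ± 0.21 on the log2 scale (979 ± 186 against 26.3 ± 7.43 CPM). CDH2 was higher by 2.18 and CDH1 lower at -0.88, and SNAI2 was lower at -2.42 (101 ± 55.6 against 538 ± 191 CPM). BMP4 was lower at -1.80 and ID2 higher at 1.38. BMP2 at 0.37, ID1 at -0.43 and ID3 at 0.10 did not pass.

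Of 27 cell cycle genes 10 were lower and 0 higher in edgeR (11 and 0 adjusted over the list alone, 12 and 0 at an unadjusted p under 0.05, 11 and 0 in DESeq2). Of 25 cytoskeleton genes 10 were higher and 1 lower (10 and 3 adjusted over the list alone), with KRT7 at 3.28, DCX at 2.84 and TMSB4X at 1.70. Of 25 matrix genes 8 were higher and 4 lower (10 and 4 adjusted over the list alone), with FBLN1 at 3.35, HAS2 at 2.23 and COL4A2 at -2.49. Of 24 guidance genes 6 were higher and 4 lower (7 and 5 adjusted over the list alone), with the semaphorin receptors NRP2 at 2.98 and NRP1 at 2.67, and SEMA3A at -2.64 and PDGFA at -2.99. Of 18 FGF genes 2 were higher and 5 lower (2 and 5 adjusted over the list alone), with FGF19 at -2.42 and FGF4 at -1.93. Of 6 Notch genes 4 were lower and 0 higher (5 and 0 adjusted over the list alone and at an unadjusted p under 0.05, 4 and 0 in DESeq2), with DLL1 at -3.99 and NOTCH1 at -2.04. Other named genes were LEFTY1 at -5.23, RSPO3 at -3.02, HOXA2 at -2.87, WNT3A at -1.90, TLL1 at 2.99, SMAD9 at 2.47 and TCF7L2 at 1.88.

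Of 9 BMP targets 2 were higher and 1 lower (ID4), and of 11 BMP ligands and receptors 5 were higher and 1 lower, the same adjusted over the list alone. Of 14 BMP antagonists and modulators 2 were higher, the antagonist NBL1 and TLL1, a tolloid-type protease that cleaves chordin, and 0 lower in edgeR (2 and 0 adjusted over the list alone, 3 and 0 at an unadjusted p under 0.05 and in DESeq2). Of 25 WNT genes 3 were higher and 6 lower (6 and 6 adjusted over the list alone), and of 18 glycolysis genes 1 and 6 (2 and 7 adjusted over the list alone). The counts were 4 and 4 of 14 epithelial junction genes, 4 and 3 of 20 EMT genes and 1 and 4 of 15 dissociation stress genes, the same adjusted over the list alone. Of 15 NODAL and TGF-beta genes 2 were higher and 1 lower (1 and 1 adjusted over the list alone). Of 9 HOX list genes HOXA2 was lower and 0 were higher in edgeR (0 and 0 adjusted over the list alone, 1 higher and 2 lower at an unadjusted p under 0.05, 0 and 2 in DESeq2).

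Over all genes 268 were higher and 244 lower of 3502 (edgeR, adjusted p under 0.05). The counts were 43 and 21 without the 2.5 h library, 115 and 96 without the 5.0 h library, 104 and 72 without the library block, 171 and 142 at Leiden resolution 2, and 564 and 597 with clustering genes scaled within each library. Without the 2.5 h library KRT7, TMSB4X, DLL1, PDGFA, HOXA2, COL4A2, NOTCH1, WNT3A, CDH1 (edgeR adjusted p 0.0556), BMP4 (0.153) and ID2 (0.128) no longer passed, nor did KRT7, NRP1 and SNAI2 (0.0673) without the 5.0 h library or HOXA2 and NOTCH1 without the 0.5 h library, while ID1 passed at -0.67 (0.0189) without the 5.0 h library. CDH2 (0.0827), HOXA2, BMP4 (0.0534) and ID2 (0.269) no longer passed without the library block, HOXA2, NOTCH1, BMP4 (0.0607) and ID2 (0.0757) at Leiden resolution 2, and COL4A2 with doublets kept. ID1 passed in DESeq2 (0.0379), and with the scaled clustering BMP2 at 0.55 (0.0289) and ID3 at 0.22 (0.00775).

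Non-neural ectoderm-like cells were compared with epiblast-like cells. The class was named from markers of non-neural or extraembryonic ectoderm, which do not tell these apart, so a split within the embryonic ectoderm is not shown. MSX1 and MSX2, targets of BMP, were higher by 2.31 ± 0.25 and 4.26 ± 0.29 on the log2 scale, with MSX1 at 882 ± 425 against 217 ± 191 CPM. BMP2 was higher by 3.26 and BMP4 by 2.23. ID1 was lower at -1.05, and ID2 (0.51) and ID3 (-0.26) did not pass. CDH1 was higher by 0.47 and CDH2 lower at -0.51, and SNAI2 did not pass (0.25, edgeR adjusted p 0.351).

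Of 9 BMP targets 3 were higher and 1 lower (4 and 2 adjusted over the list alone). Of 18 EMT genes 4 were higher and 10 lower (4 and 10 adjusted over the list alone), with CDH11 at -3.03, COL1A2 at -2.29 and VIM at -1.69. Of 17 FGF genes 1 was higher and 9 lower (2 and 11 adjusted over the list alone), with DUSP6 at -2.96, FGF13 at -1.92 and IL17RD at -1.56. Of 24 WNT genes 7 were higher and 7 lower (8 and 7 adjusted over the list alone), with WNT11 at 5.44, WNT3A at 3.17, WNT5A at 2.71, SFRP1 at -1.78, ROR2 at -1.76 and FRZB at -1.52. Of 25 matrix genes 10 were higher and 1 lower (10 and 2 adjusted over the list alone), with HAS2 at 2.33, SDC4 at 2.26 and ITGA6 at -1.52. Of 18 glycolysis genes 9 were higher and 1 lower (9 and 3 adjusted over the list alone). Of 12 BMP antagonists and modulators 3 were higher (BMPER, SOSTDC1 and TSKU) and 1 lower (the ligand ADMP), and of 11 BMP ligands and receptors 5 and 1, the same adjusted over the list alone. The counts were 7 and 8 of 25 cytoskeleton genes, 5 and 4 of 14 epithelial junction genes and 3 and 3 of 14 NODAL and TGF-beta genes, also the same over the list alone. They were 3 and 8 of 27 cell cycle genes (5 and 9 adjusted over the list alone), 7 and 3 of 22 guidance genes (7 and 5), 2 and 4 of 15 dissociation stress genes (3 and 4) and 2 and 2 of 6 Notch genes (2 and 3). Of 6 HOX list genes 4 (CDX1, CDX4, HOXA2 and HOXA4) were higher and 0 lower in edgeR (5 and 0 adjusted over the list alone, 0 lower at an unadjusted p under 0.05, 3 and 0 in DESeq2). CDX4 at 4.07, KRT7 at 3.67, HOXA2 at 3.43 and VEGFA at 2.51 were also higher, and ADMP at -2.88 and LFNG at -2.30 lower.

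Over all genes 418 were higher and 378 lower of 3458 (edgeR, adjusted p under 0.05). The counts were 197 and 176 without the 0.5 h library, 112 and 95 without the library block and 267 and 213 at Leiden resolution 2. CDH2 no longer passed without the 0.5 h library (edgeR adjusted p 0.120) or the 2.5 h library (0.0552) and was at 0.25 with clustering genes scaled within each library, SNAI2 was at -0.064 without the 5.0 h library and passed as lower at -0.94 (0.0111) with list members allowed among the clustering genes and as higher at 2.27 (0.000365) with the scaled clustering, ID2 passed at 0.76 (0.0118) without the 0.5 h library and ID3 at -0.36 (0.00752) without the 2.5 h library. ID2 also passed in DESeq2 (0.0170), with no expression filter and with list members allowed, and ID3 with no expression filter, with list members allowed and with the scaled clustering (-0.53). Without the library block MSX1 (0.0795), ADMP, COL1A2, CDH1 (0.0667), CDH2 (0.194) and ID1 (0.0807) no longer passed, and at Leiden resolution 2 IL17RD and CDH2 (0.441) did not.

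The link of EMT and BMP signalling was examined within the streak-like class by SNAI2. Of 9 measured BMP targets 2 were higher in cells with a SNAI2 UMI, ID4 by 0.37 ± 0.05 on the log2 scale (edgeR adjusted p 0.0104) and ATOH8 by 0.65 ± 0.12 (adjusted p 0.0272), both in 3 of 3 libraries. Of the 9, 0 were lower over all genes in edgeR or DESeq2, and 3 were lower at an unadjusted p under 0.05. Adjusted over the list alone 3 were higher and 3 lower. ID1 at -0.24, ID2 at -0.17 and ID3 at -0.62 did not pass over all genes (adjusted p 0.0906, 0.205 and 0.0765), and each was lower in 3 of 3 libraries. BMP2 was higher by 1.04, the receptor ACVR2B by 0.60 and the antagonist TSKU by 0.66, and ADMP was lower at -0.78. Of 18 FGF genes 5 were higher and 0 lower in edgeR (8 and 1 adjusted over the list alone, 9 and 3 at an unadjusted p under 0.05, 2 and 0 in DESeq2).

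Over all genes in edgeR, counts higher and lower were 2 and 0 of 10 BMP ligands and receptors (3 and 0 adjusted over the list alone, at an unadjusted p 3 and 0, in DESeq2 2 and 0) and 1 and 1 of 11 BMP antagonists and modulators, the latter the ligand ADMP (2 and 2 adjusted over the list alone). They were 5 and 1 of 24 WNT genes (6 and 2 adjusted over the list alone), 2 and 1 of 18 EMT genes (4 and 1), 2 and 2 of 25 matrix genes (3 and 3), 2 and 1 of 23 guidance genes (3 and 3) and 1 and 1 of 6 Notch genes (1 and 1). Counts with a 0 are followed by those adjusted over the list alone, at an unadjusted p under 0.05 and in DESeq2: 3 and 0 of 15 NODAL and TGF-beta genes (3 and 0, 5 and 1, 3 and 0), 2 and 0 of 5 HOX list genes (3 and 1, 3 and 1, 1 and 0), 2 and 0 of 24 cytoskeleton genes (3 and 2, 4 and 2, 2 and 0), 0 and 2 of 14 epithelial junction genes (0 and 3, 1 and 7, 0 and 2), 0 and 1 of 14 dissociation stress genes (0 and 3, 0 and 4, 0 and 1), 0 and 0 of 18 glycolysis genes (0 and 2, 0 and 6, 0 and 0) and 0 and 0 of 27 cell cycle genes (0 and 0, 6 and 1, 0 and 0).

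The sums held 834 cells with and 348 without a SNAI2 UMI at 0.5 h, 893 and 162 at 2.5 h, and 820 and 274 at 5.0 h. Over all genes 34 were higher and 15 lower of 3267. For part of the genes the split also followed the contrast of streak-like with epiblast-like cells. LEFTY1 at 4.54, DLL1 at 3.60, FGF4 at 2.29, FGF19 at 2.24, WNT8A at 2.03, FGF3 at 1.80, FGF8 at 1.11 and FGF18 at 0.98 were higher and HES5 at -1.16, ITGA6 at -0.84, DAG1 at -0.76 and SFRP2 at -0.49 lower, picked after their values were seen, each in the direction it had there. ADMP, higher in that contrast, was lower here at -0.78, and CHRD and MSX1, also higher there, did not pass here at 0.19 and 0.05. No tally over all genes called in both contrasts was made. The BMP target result was not separated from how far cells lie along that contrast, which was not tested and which the picked genes cannot decide. Without the library block 0 BMP targets passed in edgeR, nor did BMP2, ACVR2B, TSKU or ADMP. Without thinning 1 target was higher, ATOH8 (0.0556) and ADMP (0.0883) no longer passing, and with SNAI2 status by 2 UMIs ID3 was lower at -0.58 (0.0384). Without the 0.5 h library 2 BMP targets were lower, ID1 at -0.30 (adjusted p 0.00461) and ID3 at -0.83 (0.000376), and without the 2.5 h library ID3 was lower at -0.35 (0.0480) and ATOH8 no longer passed (0.0621).

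In a separate draw at 9000 UMIs per cell, with cells below that depth left out, SNAI2 was seen in 71.1%, 83.0% and 74.7% of streak-like cells over the 3 times, and in 98.9%, 96.5% and 89.6% of mesoderm-like cells. The shares of all cells before thinning were 80.0%, 86.1% and 82.7%, and 99.5%, 97.4% and 92.6%. In yolk sac endoderm-like cells, taken as a measure of free RNA, the shares were 10.2% (6.87 to 14.4), 6.08% (4.62 to 7.85) and 10.6% (8.40 to 13.1), at median depths of 17990, 12020 and 14617.5 UMIs against 18400, 12050 and 14021 in streak-like cells. Epiblast-like cells, at 17.2% (15.5 to 18.9), 11.4% (9.62 to 13.3) and 14.4% (12.9 to 16.1), lay above it beyond counting error at 0.5 h and 2.5 h, with overlapping intervals at 5.0 h.

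Over time, in whole libraries, NOTO, a transcription factor of the notochord, went from 20.7 CPM (19.9 to 21.5) at 0.5 h to 52.9 at 2.5 h and 90.5 (88.7 to 92.4) at 5.0 h, 4.38 times as high. CHRD went from 89.7 to 187 CPM, 2.09 times as high. ID2 went from 619 to 288 CPM, MSX2 from 34.5 to 13.1 CPM, LFNG from 202 to 71.0 CPM, HES5 from 31.5 to 15.3 CPM, JUN from 233 to 100.4 CPM and CXCR4 from 169 to 82.2 CPM. Within endoderm-like cells CXCR4 was at 1189.5, 838 and 911 CPM over the 3 times, and the share of that class was 10.3%, 4.65% and 4.50%. The BMP target list had a median log2 ratio (5.0 h over 0.5 h) of -0.66 over 9 members, below each of the 10000 random lists, and the Notch list -0.42 (percentile 0.040). The matrix list had a median of 0.30 (percentile 99.97) and the dissociation stress list 0.29 (99.8). The median of all genes was 0.049, and the 12 lists not named here lay between percentile 8.63 (glycolysis) and 95.6 (epithelial junctions).

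By the rule, 15 genes rose and 11 fell of 3045 considered. Other risers named were PCP4 (3.22 times), HIST1H2B7 (2.71), SELENOP1 (2.60), H2AFJ (2.41), CA2 (2.40), CTSH (2.35), GTF3C3 (2.30), ALCAM (2.14) and OST4 (2.11). Other fallers had ratios of 0.372 to 0.486 and were KLF6, TNNT2, PERPB, TMEM39B and VEGFA. With the 2.5 h library not used, which was chosen after seeing the data, 38 rose and 19 fell. There is no replicate of any time, and time cannot be separated from embryo or preparation, nor from sex at 2.5 h. HINTW, a gene of the W chromosome, was at 0.087 CPM at 0.5 h and 0.238 CPM at 5.0 h. The median log2 ratio (5.0 h over 0.5 h) of 151 Z-linked genes minus that of autosomal genes was -0.01 (bootstrap interval -0.06 to 0.05). These values argue against a difference of sex between 0.5 h and 5.0 h.

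Within streak-like cells, the BMP target list had a median log2 ratio of -1.22 (5.0 h over 0.5 h, 8 of 9 members below 0, lower than each of the 10000 random lists). MSX1 went from 1595 to 341 and 228 CPM, ID2 from 536 to 213 and 111 CPM, and ID4 from 603 to 249 and 201 CPM. With classes from clustering genes scaled within each library, chosen after seeing the data, the BMP target median was -1.14. In that clustering MSX1 and ID2 fell less, from 636 to 250.0 CPM (a ratio of 0.393 against 0.143) and from 338 to 115 CPM (0.341 against 0.206), while ID3 (0.531 against 0.585) and LFNG (0.237 against 0.277) fell more. CHRD went from 126 to 574 and 898 CPM, FGF18 from 38.4 to 201 and 212 CPM, and FGF8 from 42.4 to 99.6 and 205 CPM. Their sizes also depended on how the class was drawn: with the scaled clustering CHRD was 2.00 times, FGF18 1.54 times and FGF8 1.34 times as high at 5.0 h as at 0.5 h. Over the 3 times FGF18 was then at 140, 233 and 216 CPM and FGF8 at 153, 115 and 205 CPM. With 2.5 h not between the others, FGF18 and FGF8 would not meet the rule for a rise in that clustering. The median of the BMP antagonist and modulator list was 1.37 in the joint clustering and -0.13 in the scaled clustering, and that of the FGF list 0.55 and 0.03. Other lists beyond the central 95% of random lists were Notch at -1.14 (5 of 6 members below 0, lower than all random lists), EMT at 0.42 (percentile 99.91), matrix at 0.38 (99.95), BMP ligands and receptors at 0.39 (98.1), guidance at 0.35 (99.03) and glycolysis at -0.26 (0.10). In the scaled clustering the Notch, EMT and matrix medians were -0.54, 0.10 and 0.25. Markers of other parts moved in this class too, with CDX2 at 254.5, 277 and 59.4 CPM, FOXA2 at 41.8, 115 and 231 CPM and CER1 at 32.1, 46.8 and 504 CPM. By the rule 6 list members rose and 12 fell of 185 considered, PDGFRA, SFRP1 and SERPINE2 also among the former and CDX4, FGFR3, LFNG, PDGFA, FZD10, FOS and SLC2A1 among the latter. CDX4 went from 116 to 91.9 and 9.97 CPM in the joint clustering, and from 18.6 to 53.2 and 11.4 CPM in the scaled clustering.

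In mesoderm-like cells the BMP target median was -0.86 (-1.05 in the scaled clustering), again with 8 of 9 members below 0. CLDN1, which encodes a tight junction protein, went from 217 to 767 CPM and RSPO3 from 30.8 to 110.2 CPM. SEMA3A and COL4A1 rose 2.77 and 2.20 times, and TGFB1 had a ratio of 0.468, so that 4 list members rose and 1 fell of 182. The epithelial junction list had a median of 0.67 and the matrix list 0.51, each above all random lists at percentile 100. In the scaled clustering these medians were 0.45 and 0.39. Other lists beyond the central 95% of random lists were NODAL and TGF-beta at -0.21 (percentile 1.22), WNT at -0.13 (1.53) and HOX at 0.43 (97.7). Marker genes, picked after their values were seen, also differed over the 3 times in this class, with FLI1 at 42.5, 110.03 and 13.03 CPM, KDR at 205, 343 and 71.3 CPM, EOMES at 27.1, 34.02 and 70.6 CPM and DNMT3B at 331, 385 and 591 CPM. In epiblast-like cells the BMP target median was -0.36 (percentile 0.010), and -0.35 in the scaled clustering. Also beyond the central 95% of random lists were Notch at -0.70 (lower than all random lists), dissociation stress at 0.38 (99.99), FGF at 0.29 (99.4), matrix at 0.25 (99.7) and EMT at 0.26 (98.97). In these cells MSX1 went from 437 to 105 CPM and ID4 from 402 to 127 CPM, while ADMP went from 9.50 to 40.1 CPM. TAGLN, JUN, LFNG, HES5, FGFR3, KRT7 and SLC2A1 also fell, with ratios of 0.346 to 0.494, which made 2 rising and 9 falling of 155.

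**Figure D3:**
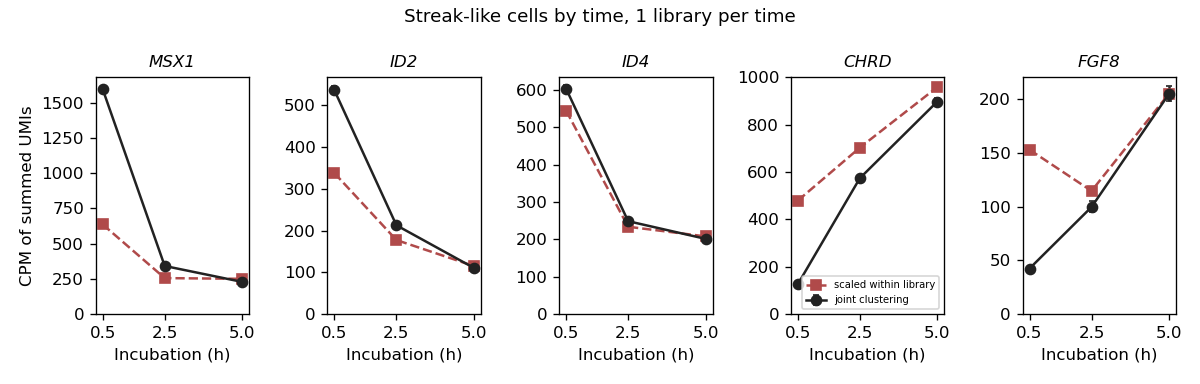
CPM of summed UMIs of 5 genes in streak-like cells against incubation time (h), 1 library per time, with classes from the joint clustering (circles, 95% counting intervals) and from clustering genes scaled within each library (squares). MSX1 went from 1595 to 228 CPM in the first and from 636 to 250.0 CPM in the second.

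The 2.5 h library stood apart. HINTW, a gene of the female W chromosome, was at 12250 CPM there against 0.087 at 0.5 h and 0.238 CPM at 5.0 h. By size, 46 genes were at least 2 times as high at 2.5 h as in both other libraries and 31 at most as low by the same factor, against 3 genes highest at 5.0 h and 5 highest at 0.5 h. Genes lowest in the other libraries were not counted. Sex-linked genes were not left out of these counts, and the W-linked HINTW and HNRNPKL are among the 46. Of 110 genes at least 2 times apart between 2.5 h and 5.0 h, 78 remained without Z-linked and W-linked genes. Part of the 46 are markers of yolk sac endoderm, such as APOB at 1.16, 50.1 and 2.82 CPM and FGB at 23.5, 202 and 66.6 CPM, and the share of yolk sac endoderm-like cells was 4.07%, 18.4% and 11.2% over the 3 times. Within that class APOB was at 24.1, 255 and 23.04 CPM and FGB at 203, 768 and 294 CPM, but 1028 of its 1099 cells at 2.5 h lay in cluster 12, which held 3 and 8 cells of the other libraries. The HOX list was higher at 2.5 h than at 5.0 h, with a median log2 ratio of 0.71 over 5 members (percentile 99.92), among them HOXB5 at 50.9 against 12.7 CPM and 17.1 CPM at 0.5 h. The members were HOXA2, HOXB1, HOXB5, CDX1 and CDX4, with ratios of 0.966, 1.37, 4.00, 1.64 and 3.29 in that order. The list median is thus the value of CDX1, and HOXA2 did not rise. By median log2 ratio of 2.5 h over 5.0 h, guidance at 0.44 (99.99), EMT at 0.38 (99.97) and WNT at 0.31 (99.96) lay further out among random lists. Also beyond the central 95% were BMP ligands and receptors at 0.42 (99.3), matrix at 0.24 (99.3) and dissociation stress at -0.28 (0.46). The rule for single genes uses this library, while the list medians of 5.0 h over 0.5 h do not.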

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

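Of 117 named class effects, 6 went in opposite directions in different libraries, each beyond counting error, and all belong to mesoderm-like against streak-like cells. The differences between libraries were not tested, since each time is 1 library. The log2 ratio of CDH2 was 1.92 at 0.5 h, 0.24 at 2.5 h and -0.51 at 5.0 h. That of SNAI2 was 1.03, -0.083 and 0.59, and that of BMP4 -1.37, -0.60 and 0.81. ID1 had log2 ratios of -0.12, 0.50 and 0.95, ID2 of -0.35, 0.59 and 1.01, and ID3 of -0.30, 0.23 and -0.38. Different clusters hold both classes in each library. The streak marker T was among the 30 leading genes of the 5.0 h mesoderm-like cluster 3 and not among those of the 5.0 h streak-like cluster 9.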

How the results depend on the processing

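The alternative denominator for shares, the time counts with the 2.5 h library not used and the list medians in the scaled clustering were chosen after seeing the data. Over the class contrasts and the SNAI2 contrast, 1235 of 1390 values of named genes kept their direction and side of the threshold, 122 no longer passed, 26 newly passed and 7 reversed. The cause was not tested in any case below, except that leaving out a library leaves fewer sums. At Leiden resolution 0.5 no class contrast could be made, since no cluster took the streak-like or non-neural ectoderm-like class. With list members allowed among the clustering genes too few streak-like cells remained at 0.5 h for the streak contrasts. The mitochondrial part of the stricter cell filter was not run. Depth limits genes of a few CPM, and the 2.5 h library is the shallowest.

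Leaving out 1 library gave 75 to 382 genes higher and 46 to 420 lower for streak-like against epiblast-like, 0 to 62 and 0 to 73 for mesoderm-like against streak-like, 43 to 258 and 21 to 178 for endoderm-like against streak-like, and 197 to 323 and 176 to 301 for non-neural ectoderm-like against epiblast-like. For BMP targets by SNAI2 status it gave 1 to 2 higher and 0 to 2 lower. In mesoderm-like against streak-like cells the log2 fold change ranged from -0.089 (without 0.5 h) to 1.13 for CDH2, from -0.93 to 0.14 (without 0.5 h) for BMP4 and from -0.30 to 0.018 (without 5.0 h) for ID3, and in non-neural ectoderm-like against epiblast-like cells from -0.064 (without 5.0 h) to 0.46 for SNAI2. Without the replicate block, genes higher and lower were 61 and 44 for streak-like against epiblast-like, 15 higher for mesoderm-like against streak-like, 104 and 72 for endoderm-like against streak-like and 112 and 95 for non-neural ectoderm-like against epiblast-like, with 0 BMP targets higher by SNAI2 status. Without thinning 1 BMP target was higher, and with SNAI2 status by 2 UMIs 1 was lower.

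In the same order of contrasts, Leiden resolution 2 gave 90 and 105, 13 and 18, 171 and 142, and 267 and 213 genes. Clustering genes scaled within each library gave 760 and 798, 666 and 606, and 564 and 597 for the first 3, and turned BMP4 in mesoderm-like against streak-like cells to 0.14 and CDH2 in non-neural ectoderm-like against epiblast-like cells to 0.25. For mesoderm-like against streak-like, DESeq2 called 234 and 186, and 44 were higher with no expression filter. With list members allowed among the clustering genes, SNAI2 in non-neural ectoderm-like against epiblast-like cells turned to -0.94 and passed (edgeR adjusted p 0.0111). In the scaled clustering the median log2 ratio (5.0 h over 0.5 h) of BMP antagonists and modulators in streak-like cells turned to -0.13 and that of EMT genes in mesoderm-like cells to 0.10.

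Shares moved beyond counting error as follows, in the order of time. At Leiden resolution 0.5, epiblast-like cells were 42.7%, 43.3% and 41.2%, streak-like cells 0%, 0% and 0%, mesoderm-like cells 33.4%, 21.6% and 33.4%, yolk sac endoderm-like cells 6.03%, 20.03% and 13.3%, and non-neural ectoderm-like cells 0%, 0% and 0%. At resolution 2, epiblast-like cells were 30.5%, 24.7% and 25.8%, streak-like cells 13.8% at 0.5 h, mesoderm-like cells 21.3% and 19.3% at 2.5 h and 5.0 h, and non-neural ectoderm-like cells 13.01% at 5.0 h. With clustering genes scaled within each library, streak-like cells were 13.4%, 18.3% and 15.01%, mesoderm-like cells 21.6% at 5.0 h, endoderm-like cells 6.98% and 3.88% at 0.5 h and 2.5 h, yolk sac endoderm-like cells 10.5% at 5.0 h, and non-neural ectoderm-like cells 9.42%, 5.02% and 10.5%. With list members allowed, epiblast-like cells were 35.4%, 24.8% and 33.6%, streak-like cells 0.0959% and 13.6% at 0.5 h and 5.0 h, mesoderm-like cells 37.5% and 21.7% at 0.5 h and 2.5 h, endoderm-like cells 6.96% at 0.5 h, and non-neural ectoderm-like cells 6.13% and 3.23% at 0.5 h and 5.0 h. With stricter cells, epiblast-like and mesoderm-like cells were 28.5% and 30.01% at 0.5 h. With doublets kept, yolk sac endoderm-like cells were 12.1% at 5.0 h. With yolk sac endoderm-like and low-UMI cells left out of the total, epiblast-like cells were 31.1%, 29.5% and 33.02%, streak-like cells 18.7%, 27.1% and 19.5%, mesoderm-like cells 32.7%, 31.3% and 30.6%, endoderm-like cells 11.6%, 6.26% and 5.50%, and non-neural ectoderm-like cells 3.08% and 8.28% at 2.5 h and 5.0 h.

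For time in whole libraries, a floor of 100 CPM gave 7 genes rising and 5 falling, a floor of 10 CPM 17 falling, a ratio of 1.5 gave 56 and 34, and with the 2.5 h library not used 38 and 19.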

Other observations

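Genes of the amino acid response were looked at after the 2.5 h library had been seen to stand apart. CHAC1 was at 111 CPM at 2.5 h against 15.2 CPM at 0.5 h and 5.42 CPM at 5.0 h, PSPH at 56.8 against 6.89 and 6.90 CPM, and ATF4 at 1372 against 652 and 797 CPM. In mesoderm-like cells CHAC1 was at 386, 28.6 and 9.77 CPM in the same order, and in streak-like cells at 26.6, 27.9 and 4.40 CPM. Its ratio of 2.5 h over 0.5 h was 13.5 in mesoderm-like and 0.955 in streak-like cells. In epiblast-like, endoderm-like, yolk sac endoderm-like and non-neural ectoderm-like cells it was 7.05, 27.1, 7.10 and 9.72. XPOT, of the same set, was at 92.2, 101 and 97.7 CPM. SMAD7B, placed on W by the gene table, was at 24.8 CPM at 2.5 h and at 0.071 and 0.067 CPM at 0.5 h and 5.0 h.

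Chosen only after their results were seen were the tests of a pool of both sexes, of class makeup and of sex behind the HOX levels, the statement on embryo, preparation and time, and the order of libraries without sex-linked genes. HINTW was at 12250 CPM at 2.5 h and nearly absent from the other libraries. Z-linked genes, present in fewer copies in females, had a median log2 ratio (2.5 h over the mean of the others) of -0.68 relative to autosomal genes (bootstrap interval -0.75 to -0.58, 151 Z-linked genes), against -0.01 for 5.0 h over 0.5 h. This is consistent with female tissue at 2.5 h and male tissue at the other times. A pool of both sexes at 2.5 h is argued against by the 0.636% of its cells (0.450 to 0.872) below 10% of the library's median HINTW level. Sex and time change together, so no other difference of this library can be assigned to either.

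Clusters of at least 90% 1 library held 73.9% of cells. Without Z-linked and W-linked clustering genes they held 72.8%, which argues against sex-linked genes as the whole source. With each cell thinned to 5000 UMIs they held 78.2%, against 78.7% for the same cells unthinned, which argues against depth. Embryo, preparation and time cannot be told apart with 1 library per time. With clustering genes scaled within each library the share was 4.65%.

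The HOX list, with CDX1 and CDX4 among the 5 members taken, had a median log2 ratio of 0.71 at 2.5 h over 5.0 h, which is the value of CDX1. Guidance, EMT and WNT lists lay at least as far out among random lists, and no explanation was tested for them. Class makeup was tested with different sets of members, and they gave opposite answers: the median within mesoderm-like cells was 1.10 over the 7 members measured there, and 0.00 over the 5 members of the whole-library value, a set taken after the first result was seen (0.02 in the scaled clustering), while within streak-like cells it was 2.40 (1.54 in the scaled clustering). Class makeup is therefore left open. An exchange of the 2.5 h and 5.0 h labels was tested by which library lies between the others. Of 110 genes at least 2 times apart between these libraries, 53 placed 5.0 h between, 4 placed 2.5 h and 53 placed 0.5 h. Without Z-linked and W-linked genes the counts were 38, 4 and 36 of 78. A single divergent library at 2.5 h would give these counts too. Among 202 genes with the highest library at least 2 times the lowest, the counts were 123, 26 and 53 in the same order. They were 101, 24 and 36 of 161 without Z-linked and W-linked genes. In this wider set 5.0 h lay between more often than 0.5 h did. A 2.5 h library equally far from both others would not give that. Sets of genes taken in different ways thus gave different answers, and an exchange is left open. Of 15 HOX list members 0 lie on Z or W, but an indirect part of sex stays open, as does an older embryo at 2.5 h, which was not tested.

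With 10 splits of 6 sums the share of splits cannot go under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. The real counts were 622 for streak-like against epiblast-like, 62 for mesoderm-like against streak-like, 512 for endoderm-like against streak-like, 796 for non-neural ectoderm-like against epiblast-like and 2 BMP targets by SNAI2 status, and the highest of the other splits was 0 in each. Every other split mixes the compared groups, so their difference enters its residual spread and holds its calls down. Some splits also put both sums of a library on 1 side, unlike the real pairing. The classes were drawn from the same cells. No conclusion is drawn from these counts.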
